A study of Homo sapiens with 6 samples.

How the data were processed

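Gene expression was measured by RNA sequencing of total RNA from 6 MDA-MB-231/RR samples, 3 control and 3 co-treated with oTR and melatonin; groups and replicate numbers were taken from the sample titles. Cells were harvested with trypsin at high confluency, per the labels' protocols. Trimmomatic 0.38, HISAT2 2.1.0, Bowtie2, SAMtools 1.9 and StringTie 2.1.3b and the genome build GRCh38 are named, without their roles, per the submitters' processing notes. Strandedness, the RNA selection and the library kit are not given in the sources used here, so overlapping and antisense genes cannot be told apart.

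The authors deposited a gene table with values headed as read counts, which are estimated counts, and with FPKM and TPM, and a transcript table with the same 3 units. The deposited counts are not counts of whole reads. Of 326895 low, non-zero transcript values, 326895 equalled the authors' FPKM times the transcript length, in a constant unit per library, after rounding up (tolerance 0.06 counts), and each of the 46427 genes held the sum of its transcripts. The estimated counts, deposited as whole numbers, were used as they stand for the gene tests. TPM, per the file headers, was used for an alternative test on the scale log2(TPM + pseudocount), and FPKM, per the file headers, only for the comparison of units. The 6 gene FPKM columns and the 6 transcript TPM columns were not used. Because reads shared between transcripts or near-identical genes were apportioned by an estimate, the variance of such genes can depart from that of counted reads. The columns' prefixes Con and Mo were read as control and as the initials of the 2 compounds, melatonin and oTR, a reading that the labels do not spell out. Gene coordinates are the span of a gene's transcripts as the deposited transcript table gives them.

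Genes with too few counts were removed with filterByExpr (minimum count 10), which left 16557. Differences were tested with edgeR 4.0.16 (quasi-likelihood test, relative log expression factors, as the labels name for the study's own normalization) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are normalized with the same factors and are given as mean ± SD over 3 libraries; errors of log2 fold changes are standard errors of the fit. The 45 gene lists, the rule for named genes and all alternatives except the trend removals were fixed before the data were examined. Of 1475 list entries, 1457 matched a symbol, 5 an older or newer symbol and 13 were second names of mitochondrial genes already in the list. Lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1, two-sided) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. The immune cell list had 2 tested members and was left untested. The genes named are the 6 largest rises and the 6 largest falls among called genes with at least 5 CPM in the higher group and no overlap between the groups. Symbols that start with LOC, LINC, MIR, SNOR, RNU or RN7, contain orf or end in -AS and a digit were left out. For the 10 lists with the smallest p, the genes named are the 2 members with the largest change in the list's direction at 1 CPM or more and the largest opposite one. A further 8 genes were chosen for the treatment. Further members are named by being called in their list.

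Alternatives were TMM factors, library size alone, DESeq2 1.42.0, voom, 3 other count filters, the replicate number as a block, each library left out in turn, the 20 most abundant genes left out of the library sizes, limma on log2(TPM + 1) and log2(TPM + 0.1), with and without a filter, and, for lists, an estimated correlation, fry and a prior count of 0.5. Removal of a length trend, a GC trend or both (a lowess curve per library, used as offsets) was added after seeing the data. GC content came from the longest GENCODE transcript of each gene and was found for 86.8% of the tested genes.

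On counts simulated for 16290 genes in the same layout, with 50 genes changed at each size, the test recovered 26 at 1.25-fold, 43 at 1.5-fold, 49 at 2-fold and 50 at 4-fold, and 18 of its 206 calls (8.74%) were false. The list test found a simulated 30-gene list shifted 1.25-fold and called 4 of 200 unchanged lists at an unadjusted p of 0.05. Genes were drawn independently and the unchanged lists at random, so these lists held no correlation between members. The simulation therefore cannot tell whether the preset correlation suits lists of co-regulated genes. A simulated length trend in 16261 unchanged genes gave 530 calls before and 4 after its removal. Transcript usage was tested on the transcript counts with diffSplice of limma after voom. In a simulation of 9569 genes, with transcripts drawn independently and usage swapped in 100 genes, it recovered 81 with 17 false calls. The tool run first, diffSpliceDGE of edgeR, recovered 52 with 64 false calls. Figures were drawn with matplotlib 3.10.9.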

Results

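RNA was sequenced from MDA-MB-231/RR cells, a radioresistant derivative of the triple-negative human breast cancer line MDA-MB-231. The 6 libraries comprised 3 controls and 3 samples labelled as co-treated with ortho-topolin riboside (oTR), an adenosine derivative of the plant cytokinin family, and melatonin, the pineal hormone. Doses and exposure times are not given in the sources used here. The deposited gene table held estimated counts, which summed to between 56521572 and 72309015 in the control libraries and between 50569611 and 72204161 in the co-treated libraries. Nothing in the labels says that the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Every pair of libraries within a group differed by more than counting noise (chi-square per degree of freedom 12.7 to 21.6), so no pair was treated as 1 library deposited again, which does not tell whether they are independent cultures. The study asked whether the pair of compounds alters the metabolome and transcriptome of these cells and acts beyond either compound alone. The 6 libraries address only the transcriptome of co-treated against control cells, since libraries of either compound alone were not analysed here.

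Co-treated cells had lower mRNA for the protein-synthesis machinery, for MYC target genes, and for oxidative phosphorylation, glycolysis and nucleotide synthesis. DNA replication genes were lower as a list, with 23 of 46 called downward and 3 upward. These list calls rest on a preset inter-gene correlation, and none passed with an estimated correlation (camera adjusted p = 0.368 to 0.456). Transcripts of CYP1A1, a monooxygenase of xenobiotic metabolism, fell most among the genes singled out by size, from 16.9 ± 0.374 to 2.62 ± 0.338 normalized CPM (SD, n = 3). The cell cycle inhibitor CDKN1A rose from 35.1 ± 2.30 to 63.8 ± 6.28 CPM, and SESN3, a stress-inducible sestrin, rose from 21.1 ± 3.25 to 53.5 ± 3.56 CPM. Of 16557 genes tested, 5578 (33.7%) changed at an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 2743 upward and 2835 downward. Most changes were small: the median fold among them was 1.24, and 121 genes rose and 177 fell by at least 2-fold. The 3 values of one group lay wholly outside those of the other for 7852 genes (47.4%), against 10% by chance, and the first principal component, with 41.0% of the variance, separated the groups. The even split depends on the processing: with library size alone 3816 genes rose and 2065 fell. On the TPM scale, with limma in place of edgeR, 4443 rose and 1276 fell. With limma-voom on the estimated counts 2724 rose and 2812 fell, which argues against the change of tool alone, although voom differs from the limma test used on TPM. On the TPM scale the median of all genes lay at +0.11 (log2), and list medians on that scale are given relative to it.

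**Figure D1:**
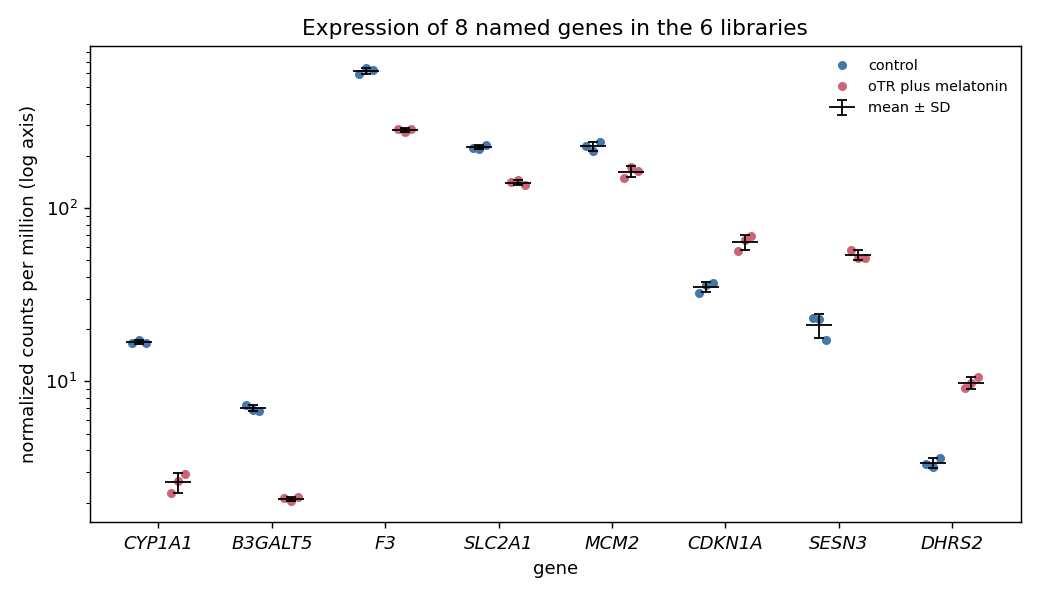
Normalized CPM (log axis) of 8 named genes in the 3 control (blue) and 3 co-treated (red) libraries, with the mean and SD of each group in black. The groups do not overlap for any of the 8 genes, with CYP1A1 at 16.9 CPM in controls and 2.62 CPM in co-treated cells.

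The genes with the largest falls were largely of low abundance. CYP1A1 (gene ID 1543, chromosome 15, 74719542 to 74725528 on GRCh38) fell by 2.68 ± 0.10 on the log2 scale (SE; edgeR adjusted p = 2.18e-07). KRTAP2-3, a keratin-associated protein gene with near-identical neighbours whose reads can be shared, fell by 1.76 ± 0.09 on the log2 scale (SE, edgeR adjusted p = 1.93e-06). B3GALT5, a galactosyltransferase of glycan synthesis (gene ID 10317, chromosome 21, 39612940 to 39673137), fell by 1.73 ± 0.10 on the log2 scale (SE), to 2.11 ± 0.0567 CPM. FBLN1, which encodes the extracellular matrix protein fibulin, fell from 8.95 ± 0.608 to 2.93 ± 0.166 CPM. CFAP251, a cilia- and flagella-associated gene, had a log2 fold change of -1.50 ± 0.11 and UCN2, a peptide hormone of the corticotropin-releasing family, one of -1.48 ± 0.12 (SE; edgeR adjusted p = 8.56e-06 and 1.85e-05).

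Among the largest rises, DHRS2, a mitochondrial and nuclear short-chain reductase (gene ID 10202, chromosome 14, 23630115 to 23645639), rose from 3.38 ± 0.210 to 9.81 ± 0.748 CPM, a log2 fold change of 1.54 ± 0.10 (SE; edgeR adjusted p = 4.48e-06). DPYSL3, a cytoskeletal regulator of the collapsin response mediator family, rose from 3.35 ± 0.204 to 9.41 ± 0.626 CPM. SESN3 (gene ID 143686, chromosome 11, 95165513 to 95232536) rose by 1.34 ± 0.10 on the log2 scale (SE; edgeR adjusted p = 9.14e-06). The other three were RNA18SN1, RNA18SN2 and RNA18SN3, near-identical copies of the 18S ribosomal RNA gene on chromosome 21 between which reads cannot be assigned. Their log2 fold changes were 1.45 ± 0.38, 1.53 ± 0.37 and 1.56 ± 0.38 (SE; edgeR adjusted p = 0.0139, 0.00947 and 0.00979). Nuclear ribosomal RNA made up 0.294% to 0.370% of the counts in the controls and 0.551%, 1.07% and 0.479% in co-treated replicates 1, 2 and 3. Without co-treated replicate 2 the 18S changes were 0.75, 0.87 and 0.90, all still called. RNA18SN1 was not called with DESeq2 (log2 fold change 1.44, adjusted p = 0.0644) or without control replicate 1 (1.22 ± 0.42, SE; edgeR adjusted p = 0.0563), at rises close to the main one.

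The gene lists fixed before the data were examined gave 15 of 44 changed (camera with a preset inter-gene correlation of 0.01, Benjamini-Hochberg), 11 downward and 4 upward. None passed with a correlation estimated from the residuals, where the smallest adjusted p was 0.368. The list test compares a list with all other genes, and list members share regulation, so the preset value sets how much 1 coordinated group counts for.

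Genes of protein synthesis fell together. Of 77 cytosolic ribosomal protein genes, 74 fell and 0 rose (75 and 0 adjusted over the list alone), with a median log2 fold change of -0.31 (camera adjusted p = 2.41e-18; adjusted p = 0.456 with an estimated correlation). RPL38 went from 321 ± 35.8 to 214 ± 11.3 CPM and RPL37 from 599 ± 80.0 to 402 ± 30.2 CPM. Reads of ribosomal protein genes can be shared with their many processed pseudogenes. With the length trend described further on removed, their median was -0.16, with both length and GC trends removed it was -0.13, and RPL12, RPL39 and RPS27 were among members that then lay above 0. Of 48 ribosome biogenesis genes, 41 fell and 0 rose (44 and 0 adjusted over the list alone), with a median log2 fold change of -0.35 (camera adjusted p = 8.38e-16, and adjusted p = 0.368 with an estimated correlation). Among them FBL, the methyltransferase of box C/D small nucleolar particles, fell from 205 ± 13.4 to 137 ± 7.12 CPM and PPAN, a factor of large-subunit assembly, from 42.1 ± 2.63 to 27.8 ± 3.47 CPM. Of 20 cytosolic aminoacyl-tRNA synthetases, 10 fell and 0 rose (10 and 0 adjusted over the list alone), with a median log2 fold change of -0.12 (camera adjusted p = 0.000505, and adjusted p = 0.368 with an estimated correlation). VARS1 and KARS1 had log2 fold changes of -0.47 ± 0.05 and -0.40 ± 0.04 (SE; edgeR adjusted p = 7.82e-05 and 7.33e-05). On the TPM scale the synthetases' median was +0.02, or -0.09 relative to all genes.

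Of 30 MYC target genes, 27 fell and 0 rose (28 and 0 adjusted over the list alone), with the lowest median of the 15 lists, -0.42 (camera adjusted p = 3.11e-13; adjusted p = 0.368 with an estimated correlation). MYC itself was among the members that fell. The list shares FBL, NOP56, NOP16, NCL, NPM1, BOP1 and RRP9 with ribosome biogenesis. It also shares CAD, PAICS, GART and NME1 with nucleotide synthesis, and LDHA and HK2 with glycolysis, so its fall is not separate from theirs. HSPE1, a mitochondrial co-chaperonin, fell from 219 ± 15.2 to 138 ± 11.9 CPM, and the transcription factor gene TFAP4 from 22.5 ± 0.840 to 14.1 ± 1.29 CPM.

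Transcripts of energy metabolism genes fell in several branches. Of 71 nuclear-encoded oxidative phosphorylation genes, 49 fell and 0 rose (54 and 0 adjusted over the list alone), with a median log2 fold change of -0.25 (camera adjusted p = 1.20e-12, and adjusted p = 0.456 with an estimated correlation). The ATP synthase subunit genes ATP5MC1 and ATP5ME had log2 fold changes of -0.83 ± 0.06 and -0.66 ± 0.09 (SE), and ATP5MC1 went from 75.1 ± 3.54 to 42.3 ± 3.26 CPM. With the length trend removed the median of this list was -0.11, and members such as COX5B lay above 0. Of the 13 mitochondrially encoded mRNAs, 5 fell and 1 rose, and that list did not pass (median -0.14; camera adjusted p = 0.121). Their median was 0.06 with the length trend removed and 0.07 with both trends removed, where COX2, COX3 and ND4L lay above 0, and the list passed with only the GC trend removed (camera adjusted p = 0.0472). Of 25 glycolysis genes, 17 fell and 1 rose (18 and 1 adjusted over the list alone), with a median log2 fold change of -0.24 (camera adjusted p = 3.11e-06, and adjusted p = 0.368 with an estimated correlation). The glucose transporter gene SLC2A1 fell from 225 ± 6.35 to 140 ± 4.76 CPM and PGAM1, a phosphoglycerate mutase, from 1017 ± 39.8 to 723 ± 25.9 CPM. The transporter gene SLC2A3 rose from 34.2 ± 2.45 to 40.04 ± 2.47 CPM (edgeR adjusted p = 0.0225), a call lost without control replicate 3 (log2 fold change 0.17, adjusted p = 0.0797), co-treated replicate 1 (0.18, 0.0687) or co-treated replicate 3 (0.24, 0.0523). Of 31 genes of the tricarboxylic acid cycle, 16 fell and 3 rose (18 and 3 adjusted over the list alone), with a median log2 fold change of -0.14 (camera adjusted p = 0.0126, and adjusted p = 0.456 with an estimated correlation). SDHB, of succinate dehydrogenase, and IDH3G, of the NAD-dependent isocitrate dehydrogenase, fell by 0.43 ± 0.05 and 0.35 ± 0.06 on the log2 scale, while IDH2, the NADP-dependent mitochondrial enzyme, rose by 0.50 ± 0.08 (SE; edgeR adjusted p = 0.000165, 0.00117 and 0.000857).

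The lists of nucleotide synthesis and DNA replication genes also fell. Of 33 purine and pyrimidine synthesis genes, 24 fell and 0 rose (25 and 1 adjusted over the list alone), with a median log2 fold change of -0.27 (camera adjusted p = 1.02e-06, and adjusted p = 0.368 with an estimated correlation). NME1, a nucleoside diphosphate kinase, fell from 207 ± 14.5 to 132 ± 11.8 CPM and CDA, which deaminates cytidine, from 2.27 ± 0.367 to 1.40 ± 0.102 CPM. The CDA call was lost with length and GC trends removed (log2 fold change -0.46, edgeR adjusted p = 0.0688) and on the TPM scale without a filter (-0.47, limma adjusted p = 0.0665). Of 46 genes of DNA replication and the G1/S transition, 23 fell and 3 rose (23 and 4 adjusted over the list alone), with a median log2 fold change of -0.11 (camera adjusted p = 0.000327, and adjusted p = 0.368 with an estimated correlation). On the TPM scale this median was +0.01, or -0.10 relative to all genes. The 3 members that rose in the main fit were DSCC1, E2F1 and PCNA. The helicase subunit gene MCM2 fell from 227 ± 13.2 to 162 ± 11.9 CPM and UHRF1, which recruits maintenance DNA methylation, from 234 ± 14.2 to 171 ± 4.25 CPM. DSCC1, a subunit of a clamp loader, rose by 0.19 ± 0.05 (SE; edgeR adjusted p = 0.0178), and lost its call without control replicate 1 (0.0727), control replicate 3 (0.0553) or co-treated replicate 3 (0.0774), at log2 fold changes of 0.165, 0.179 and 0.173. Of 53 mitosis and G2/M genes, 17 fell and 5 rose, and that list did not pass (median -0.06; camera adjusted p = 0.0809). It passed without co-treated replicate 1 (0.0136), with no count filter (0.0494) and with the GC trend removed (0.00988). With library size alone its median was 0.003, still below the median of all genes in that setting, 0.06. The proliferation marker MKI67 fell from 806 ± 25.9 to 707 ± 37.6 CPM (edgeR adjusted p = 0.0116). That call was lost with library size alone (log2 fold change -0.13, edgeR adjusted p = 0.0547) and on the TPM scale (-0.07, limma adjusted p = 0.381). It was also lost without control replicate 1 (-0.17, 0.0591) or co-treated replicate 3 (-0.17, 0.0524). The median of all genes was 0.06 with library size alone and 0.11 on the TPM scale, so the smaller falls of MKI67 there include a shift shared by all genes.

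Of 26 YAP/TAZ targets, 11 fell and 3 rose (13 and 3 adjusted over the list alone), with a median log2 fold change of -0.11 (camera adjusted p = 0.0184, and adjusted p = 0.368 with an estimated correlation). On the TPM scale their median was +0.03, or -0.08 relative to all genes. F3, which encodes tissue factor, the initiator of coagulation, fell from 621 ± 25.6 to 282 ± 7.24 CPM, and FJX1 fell from 50.07 ± 1.38 to 31.7 ± 0.609 CPM. NT5E, the ecto-enzyme that forms extracellular adenosine, rose from 781 ± 10.2 to 1172 ± 52.1 CPM. Of 22 heat shock genes, 13 fell and 4 rose (13 and 4 adjusted over the list alone), with a median log2 fold change of -0.18 (camera adjusted p = 0.0460, and adjusted p = 0.665 with an estimated correlation). HSPB8, HSPB1, HSPD1 and HSP90AB1 were among those that fell, and the 4 that rose were HSPA1A, HSPA1B, DNAJB1 and DNAJB4, of which the first pair are near-identical copies. The heat shock call was lost without control replicate 1 (0.0793), control replicate 3 (0.0852), co-treated replicate 2 (0.0840) or co-treated replicate 3 (0.0544), with medians between -0.15 and -0.19.

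The 4 lists that rose held stress and growth-control genes. Of 25 genes of energy stress and glucose sensing, 12 rose and 3 fell (12 and 3 adjusted over the list alone), with a median log2 fold change of 0.12 (camera adjusted p = 0.0272, and adjusted p = 0.393 with an estimated correlation). SESN3, SESN1, PDK4, FOXO1 and the AMP-activated kinase subunit genes PRKAA1 and PRKAA2 were among those that rose. TXNIP, a glucose-induced inhibitor of thioredoxin, fell from 83.3 ± 1.98 to 50.7 ± 1.21 CPM (edgeR adjusted p = 4.48e-06). Of 27 p53 target genes, 12 rose and 2 fell (12 and 2 adjusted over the list alone), with a median log2 fold change of 0.16 (camera adjusted p = 0.0482, and adjusted p = 0.368 with an estimated correlation). CDKN1A changed by 0.86 ± 0.07 on the log2 scale (SE; edgeR adjusted p = 2.64e-05), and TP53INP1, PMAIP1 and SESN1 rose as well. Of 55 autophagy and lysosome genes, 17 rose and 3 fell (22 and 4 adjusted over the list alone), with a median log2 fold change of 0.10 (camera adjusted p = 0.0272, and adjusted p = 0.368 with an estimated correlation). OPTN, NEU1, MAP1LC3B and ULK1 were among those that rose. Of 31 immediate early genes, 14 rose and 5 fell (15 and 5 adjusted over the list alone), with a median log2 fold change of 0.27 (camera adjusted p = 0.0379, and adjusted p = 0.665 with an estimated correlation). FOS, JUNB, EGR1 and DUSP1 rose, and MYC, FOSL1 and JUN fell. All 4 calls were lost without control replicate 1 (camera adjusted p = 0.0661 to 0.0965) and without co-treated replicate 3 (0.0544 to 0.0740), with medians of 0.09 to 0.22 and 0.09 to 0.34, none of them reversed. Without control replicate 2 the immediate early (0.0729) and autophagy (0.0509) calls were also lost, as was the p53 call without co-treated replicate 1 (0.0589). With library size alone the p53 (0.0527) and immediate early (0.0649) calls were lost. Their medians there were 0.22 and 0.33, with the median of all genes at 0.06.

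**Figure D2:**
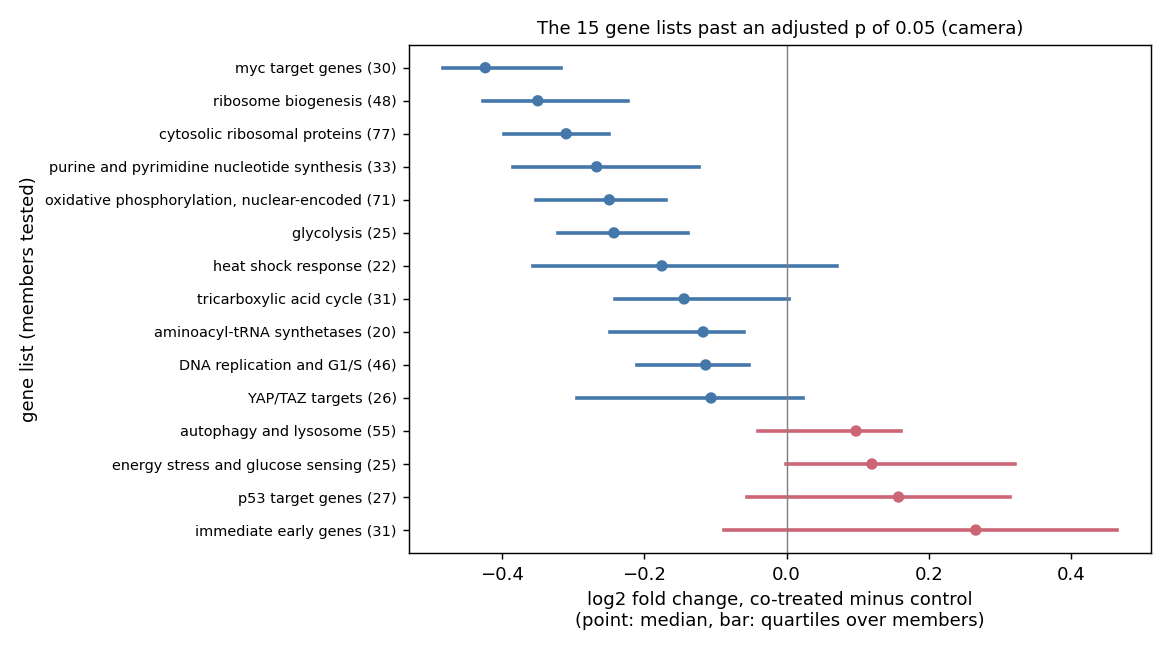
Median log2 fold change (co-treated minus control) of the 15 gene lists past the threshold, with bars between the quartiles over the members and the number of members tested in parentheses. MYC targets have the lowest median (-0.42) and immediate early genes the highest (0.27). The medians of DNA replication, aminoacyl-tRNA synthetases and YAP/TAZ targets turn to between +0.01 and +0.03 on the TPM scale, where all genes lie at +0.11.

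Genes fixed for their relation to the treatment gave mixed results. HMOX1, a heme oxygenase of the oxidative stress response, fell from 15.5 ± 1.04 to 12.1 ± 0.595 CPM (edgeR adjusted p = 0.00348). NQO2, a quinone reductase that binds melatonin, rose from 22.97 ± 2.08 to 29.9 ± 1.00 CPM (edgeR adjusted p = 0.00214). The stress transcription factor genes DDIT3 and ATF3 did not pass, at -0.17 ± 0.09 and -0.01 ± 0.14 on the log2 scale (SE; edgeR adjusted p = 0.189 and 0.969). ADK, which encodes the kinase that phosphorylates adenosine and its analogues, did not pass either, at -0.06 ± 0.06 (SE; edgeR adjusted p = 0.422).

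Fold changes followed transcript length and GC content. Across 13058 protein-coding genes, Spearman's rho between log2 fold change and the length of the expressed transcripts was 0.28, a correlation across genes, which are not independent replicates. The median was -0.15 in the shortest of 8 classes and 0.12 in the longest. The length trend was strongest in control replicate 3 and co-treated replicate 1, where each library's deviation from the mean of all 6 had a rho with length of -0.38 and 0.36. Across the 12949 of these genes with a GC value, rho between log2 fold change and GC content was -0.23, and in the same 2 libraries the deviation had a rho with GC of 0.39 and -0.41. The median deviation of ribosomal proteins was also largest in these libraries, 0.24 and -0.24, against 0.14 and 0.09 in the other controls and -0.13 and -0.12 in the other co-treated libraries. The length trend moved with the lists of short genes: the median member length was 879 bases for ribosomal proteins and 878 for oxidative phosphorylation. After removal of the length trend, a step chosen after seeing the data, their median log2 fold changes were -0.16 and -0.11. The energy stress (camera adjusted p = 0.0605) and p53 (0.0584) calls were then lost. The energy stress median hardly moved, from 0.12 ± 0.46 to 0.11 ± 0.44 (SD over members), and the p53 median went from 0.16 ± 0.30 to 0.11 ± 0.30. Why these calls were lost was not tested.

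**Figure D3:**
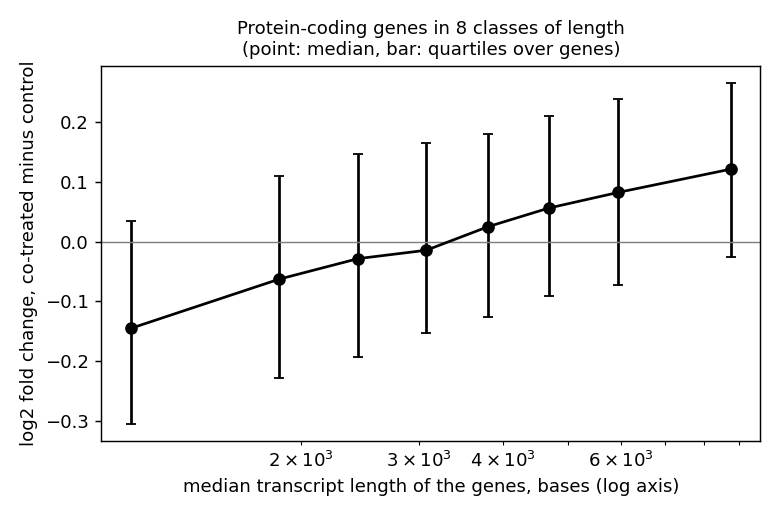
Median log2 fold change (co-treated minus control, with quartiles over genes as bars) of protein-coding genes in 8 classes of equal size by transcript length (bases, log axis). The median goes from -0.15 in the shortest class to 0.12 in the longest.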

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

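The transcript table, which the comparison of genes does not use, held more changes in transcript usage between the groups than between other groupings of the libraries with one tool, limma, but not with edgeR. Of 9961 genes with several expressed transcripts, 225 had a change in transcript usage (limma diffSplice, Simes adjusted p of at most 0.05), and 71 of them had transcripts past the threshold in both directions. Of the 225, 104 also changed in total. In FN1, which encodes fibronectin, 1 annotated transcript went from 44.7 ± 10.4% to 7.79 ± 2.00% of the gene's counts (SD, n = 3). In MYADM, a gene of membrane organisation, the main transcript went from 41.5 ± 2.05% to 63.9 ± 2.38% and another from 25.4 ± 3.61% to 3.70 ± 3.19%. In PPFIA1, a liprin scaffold gene, 1 transcript went from 81.4 ± 9.84% to 16.5 ± 7.20% and another from 2.34 ± 4.06% to 46.9 ± 7.15%. In PEF1, a calcium-binding protein gene, 1 transcript went from 91.3 ± 3.42% to 48.1 ± 13.9%. These are the first 4 genes by adjusted p among those with changes both ways, a choice made after their values were seen.

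The usage test by limma was chosen after the first tool's result had been seen. With limma, 1 of the 10 splits of the 6 samples into 3 and 3, the real one, gave 225 genes or more, and the highest of the others gave 112. With edgeR's diffSpliceDGE, which made more false calls on simulated data, 94 genes passed in the real split and 126 in the highest other. Of the 10 splits, 5 gave 94 genes or more, the real one among them. A set of 10 splits is too small for a share under 0.05. With 17 of 98 calls false on simulated data, single genes of the 225 are uncertain, and estimated transcript counts can switch between similar transcripts of a gene from library to library. The simulation drew each transcript independently and held no such switching, so its share of false calls may be too low for these data. With limma the other splits gave 74 to 112 genes, although mixed splits still hold part of the real difference. No biological explanation was tested.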

How the results depend on the processing

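The count of changed genes stayed within 1.5 times 5578 in the alternatives run, from 4178 (TPM without a filter) to 6367 (replicate block), and the number of lists stayed at 10 to 19 except with an estimated correlation (0 lists, 0 up and 0 down) and with fry (28 lists, 12 up), which asks another question. Of the single lists and named genes, none passed the threshold in the opposite direction; over all alternatives 38 list calls and 21 gene calls were lost, and 23 and 1 gained. With library size alone 2 lists rose. DESeq2 put 75 genes up and 112 down by at least 2-fold, against 121 and 177. On the TPM scale 4443 genes rose and 1276 fell with a pseudocount of 1 (17 and 24 by at least 2-fold), 4434 and 1274 with 0.1 (69 and 54), and 3210 and 968 without a filter (11 and 24); a pseudocount shrinks the folds of low genes by construction, and the cause of the other differences was not tested. Without each library in turn, 4223 to 4820 genes changed, 105 to 134 rose and 144 to 171 fell by at least 2-fold, and 10 to 16 lists passed, with 0 to 5 upward. The 0 upward lists came without control replicate 1 and without co-treated replicate 3, and 2 came without control replicate 2.

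The titles give both groups the numbers 1 to 3, but same-numbered samples did not deviate together (correlations of 0.07, 0.00045 and -0.04 across genes), and not every sample correlated best with its own number. With the number as a replicate block, 6367 genes changed and 12 lists passed, of which 2 were upward. The calls not made there were those of p53 targets (camera adjusted p = 0.106), heat shock (0.0524) and immediate early genes (0.0524), whose medians of 0.16, -0.18 and 0.28 stayed close to the main ones. Calls of CDA (edgeR adjusted p = 0.0688) and heat shock (camera adjusted p = 0.0506) were lost with length and GC trends removed together. The heat shock median went from -0.18 to -0.15 there, and the log2 fold change of CDA from -0.69 to -0.46. On TPM without a filter, CDA, HMOX1, RPL37 and the 18S genes were not called, the latter at log2 fold changes of 1.44 to 1.59. Removing the GC trend brought in mitosis (camera adjusted p = 0.00988), mitochondrially encoded mRNAs (0.0472), MAPK feedback genes (0.0242), TGF-beta targets (0.0429) and ADK (log2 fold change -0.12; edgeR adjusted p = 0.0388). At these depths the test recovered 26 of 50 genes with the smallest simulated change, so small changes can be missed. The simulation held far fewer changed genes than were called here (206 calls against 5578). Its adjusted threshold was therefore stricter, and its recovery is no measure of that in the data.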

Other observations

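Several fixed lists that did not pass as a whole held members that moved apart. Of all 16557 tested genes, 2743 rose and 2835 fell (33.7% called), so a list can hold members on both sides without a change of its own. Of 35 genes of endoplasmic reticulum chaperones and the unfolded protein response, 10 rose and 10 fell (camera adjusted p = 0.704). Those that rose included HERPUD1 and SEL1L, which act in degradation of misfolded proteins, but also the co-chaperone genes DNAJB9 and DNAJC3 and the oxidase gene ERO1B. Those that fell included the folding factors CALR, HSP90B1, PDIA4 and HSPA5. No division of the list by function was tested. Of 32 NF-kB and inflammatory genes, 8 rose and 8 fell (camera adjusted p = 0.731), with the cytokine genes IL1A, CSF2, CCL2 and LIF lower and CSF1 higher, and the inhibitor genes NFKBIA higher and TNFAIP3 lower. Of 34 hypoxia targets, 13 fell and 6 rose (camera adjusted p = 0.237), and CA9, a carbonic anhydrase, had a log2 fold change of -2.19 ± 0.28 (SE; edgeR adjusted p = 0.000255) at 1.22 CPM in controls. Of 37 genes of homologous recombination and Fanconi anemia repair, 9 rose, BRCA1 and ATM among them, and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.237). The median of this repair list was 0.06, and 0.03 with the length trend removed. With length and GC trends removed it was 0.01, the same as the median of all genes there (0.01). Of 53 glycerophospholipid and sphingolipid genes, 21 rose and 6 fell (camera adjusted p = 0.121). Interferon-stimulated genes (11 up and 3 down of 37), TGF-beta and SMAD targets (11 up and 6 down of 30), MAPK feedback genes (10 up and 3 down of 20) and ATF4 targets (5 up and 9 down of 43) did not pass camera either (adjusted p = 0.116, 0.106, 0.106 and 0.121). Of these, interferon genes passed without co-treated replicate 1 (0.0466), with the length trend removed (0.0436) and with both trends removed (0.0303). TGF-beta targets passed without control replicate 3 (0.0499) and with the GC trend removed (0.0429), and MAPK feedback genes with the GC trend removed (0.0242).

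Of 19 circadian and melatonin-related genes, 5 rose and 7 fell (camera adjusted p = 0.731). The largest falls were those of CYP1A1 (log2 fold change -2.68) and CYP1B1, followed by PER3, TEF, NR1D1, PER2 and CRY1. BHLHE40, NQO2, NFIL3, CRY2 and CLOCK rose, so clock genes moved both ways. The median of the 19 genes was 0.10, while their mean (-0.16) and their test were negative. Median, mean and test also differed in sign for the lists of NRF2 targets (11 up and 8 down of 32), NF-kB genes, fatty acid synthesis (6 up and 3 down of 21), histones (2 up and 1 down of 19), polyamine and urea cycle genes (7 up and 7 down of 21), mesenchymal genes (7 up and 9 down of 37), and fibroblast and endothelial markers, none of which passed camera. Markers of other cell types showed no list-wide change: 4 of 15 luminal epithelial markers rose and 4 fell, 1 of 5 fibroblast and 1 of 6 endothelial markers fell, and 2 of the immune markers were expressed enough to test. Pro-apoptotic genes (7 up and 3 down of 29) and anti-apoptotic genes (2 up and 2 down of 18) did not pass (camera adjusted p = 0.426 and 0.890).

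The tests of 18S ribosomal RNA below and every removal of a length or GC trend were chosen after the results were seen. The count of 5578 changed genes was reached by 1 of the 10 splits of the 6 samples into 3 and 3, the real one, and the highest of the others gave 2. For gene lists, 1 split, the real one, gave 15 or more, and the highest of the others gave 10. A set of 10 splits cannot give a share under 0.05. Mixed splits still hold part of the real difference, so their lists are no measure of false calls.

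The pattern with the smallest p was the joint fall of ribosomal proteins, ribosome biogenesis, MYC targets, oxidative phosphorylation, nucleotide synthesis and glycolysis. None of the 6 calls held with an estimated correlation (camera adjusted p = 0.368 to 0.456). The MYC list shares members with ribosome biogenesis, nucleotide synthesis and glycolysis, so the 6 lists are not 6 separate groups of genes. A length trend, a GC trend or both together are argued against as the whole cause, since under the preset correlation 6 of the 6 lists stayed past the threshold and downward after each removal. The length trend may account for part of it, as the median of ribosomal proteins went from -0.31 to -0.16 and that of oxidative phosphorylation from -0.25 to -0.11 without it. A single library is argued against too as the whole cause. Under the preset correlation, the fewest lists kept when any 1 library was left out was 6 of 6. The lists had been chosen by p from the same libraries, so keeping the threshold is weak evidence. Their medians stayed negative as well, with ribosomal proteins between -0.35 and -0.29 in these fits. That the co-treatment lowers expression of growth genes remains a hypothesis, and differences in confluency or harvest between the groups stay open and untested.

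The rise of 18S ribosomal RNA followed the groups in all 6 libraries but with a narrow gap. Summed over the 3 copies it was 517 ± 203 CPM in controls and 1473 ± 957 CPM in co-treated cells (SD, n = 3), and the lowest co-treated library lay 1.14 times above the highest control, a gap smaller than the control SD, while 28S went from at most 2585 CPM in controls to at least 3025 CPM and 45S overlapped between the groups, at 621, 659 and 626 CPM in controls and 652, 1786 and 674 CPM in co-treated replicates 1, 2 and 3. Without co-treated replicate 2, which adds to the size, the lowest of the 3 log2 fold changes was 0.75 ± 0.23 (SE). Without control replicate 1 it was 1.22 ± 0.42 (SE). The copies had been chosen for groups that do not overlap, so these fits are weak evidence against a single library as the whole cause. Carry-over of ribosomal RNA that differs between libraries stays open, since 45S was clearly raised in 1 library only. The co-treated libraries also varied 25.3 times more in 18S than in GAPDH (SD of log2 CPM). The ordering of the groups does not count against carry-over, because the rule that named the 3 copies asked for no overlap. The labels do not tell how ribosomal RNA was removed, so carry-over and a change in the cells cannot be told apart.

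A first hypothesis of a regulator was that CYP1A1 and CYP1B1, classic targets of the aryl hydrocarbon receptor, fell because its activity may be lower. CYP1B1 fell by 1.04 ± 0.07 on the log2 scale (SE, edgeR adjusted p = 4.57e-06). Of 7 other targets tested, AHRR, TIPARP, ALDH1A3 and NFE2L2 fell and EREG and LMCD1 rose. The list did not pass (camera, adjusted p = 0.151 over both regulator lists and 0.151 before adjustment). The bound set beforehand counted a p above 0.05 against the hypothesis, but with 7 genes such a p excludes nothing, so it stays open. The repressor gene AHRR, a direct target, went from 27.5 ± 2.37 to 11.3 ± 1.92 CPM.

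A further hypothesis was that SESN3, PDK4 and IRS2 rose with higher activity of FOXO transcription factors. Of 13 other FOXO targets tested, 8 rose (INSR, CCNG2, CDKN1B, BCL6, RICTOR, PIK3CA, CAT and PINK1) and 0 fell, with a median log2 fold change of 0.25. The list passed (camera, adjusted p = 0.00926 over both regulator lists and 0.00463 before adjustment). With length and GC trends removed the p was 0.00867, and with an estimated correlation it was 0.173. The result is in line with the hypothesis under the preset correlation, but the list was written after the rise of the 3 genes had been seen, and protein activity was not measured.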
